A study of Arabidopsis thaliana with 18 samples.

How the data were processed

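RNA from whole Arabidopsis thaliana Col-0 seedlings was measured by RNA-seq in 18 libraries, 6 for each of 3 groups: seedlings without bacteria, seedlings with the synthetic community SynCom5-S1, whose strains the labels call suppressors, and seedlings with SynCom5-NS1, whose strains the labels call non-suppressors. The strains of the communities are not named in the sources used here. Each group holds 3 biological replicates from each of 2 independent experiments, A and B, per the series' design text. Per the labels' protocols, seeds germinated on Johnson medium for 7 days under 16 h of light and 8 h of dark, seedlings were moved to plates with or without a community, and whole seedlings were harvested 12 days later under 9 h of light and 15 h of dark, at 21 °C by day and 18 °C by night. Non-stranded libraries were made from poly(A) RNA isolated from 1000 ng of total RNA, per the labels' protocols.

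The authors deposited 1 table of whole-number read counts per gene, not normalized, for 27206 loci and 18 libraries. Per the submitters' processing notes, bcl2fastq 2.20.0, FastQC, Trimmomatic, HISAT2 and featureCounts from Subread were used with the TAIR10 genome build, and the versions of the tools other than bcl2fastq are not given in the sources used here. All 18 count columns matched 1 sample title each, so 0 columns were left without a sample. The table lists loci of the 5 nuclear chromosomes, and 100% of its identifiers have the form of nuclear loci. How featureCounts treated reads that fall on overlapping genes or on several places is not given in the sources used here. Without strand in the libraries, reads from a gene and from a gene on the opposite strand cannot be told apart. Symbols and gene models came from the RefSeq annotation of TAIR10.1, which is not the build named by the submitters, so no coordinates are printed, and 26719 of the 27206 loci matched it by locus tag.

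Counts were tested as deposited with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr over the groups, which left 17627 genes after 4078 loci with 0 counts in all libraries and other low loci were removed. Library sizes were scaled with TMM, and 1 quasi-likelihood model (glmQLFit and glmQLFTest, robust) with group and experiment as additive terms was fitted to all 18 libraries, which left 14 residual degrees of freedom. The 3 contrasts were SynCom5-S1 against no bacteria, SynCom5-NS1 against no bacteria and SynCom5-S1 against SynCom5-NS1. P-values were adjusted by Benjamini-Hochberg per contrast, and a gene with an adjusted p under 0.05 was called. Standard errors (SE) of log2 fold changes were taken as the fold change divided by the square root of the quasi-likelihood F. Each experiment was also fitted alone, and the difference of each contrast between experiments was tested as an interaction term. Levels are CPM, the counts scaled to a library size of 1000000 with the TMM factors, as mean ± SD with n = 6 libraries per group.

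A total of 20 gene lists with 428 distinct loci found in the table were tested with camera from limma 3.58.1 at its preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over 60 tests. Camera compares the shift of a list's genes with that of all other genes. The tests were repeated with a correlation estimated for each list and with fry, which tests whether a list's genes move, on balance, in 1 direction and does not compare them with other genes. Members were counted over all genes tested and adjusted over the list alone. The lists were MAMP response, pattern receptors and signalling, salicylic acid, jasmonate, ethylene and defensins, indole glucosinolate and camalexin, aliphatic glucosinolate, phosphate starvation, iron deficiency, sulphur starvation, nitrogen, auxin response, abscisic acid and drought, flavonoid and anthocyanin, hypoxia, photosynthesis, root hair, root endodermis and suberin, cell cycle, and circadian clock. The photosynthesis list stood for green shoot tissue, the root hair and endodermis lists for root cell types, the cell cycle list for meristems and the circadian list for the hour of harvest. The groups, the contrasts, the model, the gene lists, the rule for named genes and the alternatives other than those named as added were chosen before the data were examined.

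The rule for named genes took, per contrast, the 8 genes with the largest positive and the 8 with the largest negative log2 fold change among called genes with a mean log2 CPM of at least 1, the same sign in both experiments and a symbol in the reference. It also took up to 4 called members with the largest absolute fold change of each list called by camera, or the 2 members with the smallest p where no member was called, given as values only. Of the genes called in the interaction test, up to 3 with a symbol were taken per contrast. Among the largest changes, genes without a symbol were passed over. With SynCom5-S1 these were 8 among the increases and 4 among the decreases, and with SynCom5-NS1 4 and 8. Between the communities they were 13 among genes higher and 6 among genes lower with SynCom5-S1. Other genes are named where a count of 5 or fewer would otherwise stand without its members. Some called members of the iron list and of the gene families are named as well. All of these were chosen after their values were seen. The values of 1 gene that the rule takes are not reported here.

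The overlap of both contrasts against the shared control libraries was set beside 20 simulations with unchanged groups, beside the overlap of independent lists and beside 9 divisions of the controls into sets of 3 libraries, each set used for 1 community. A fold against a group with 0 counts in all libraries was bounded with a floor of 3 counts over the group, and ratios of group totals with few counts have exact 95% intervals. Intervals and floors cover counting error only. Transcripts of 246 genes (the named genes, the called members of the lists and of gene families described further on, and 3 ferritin genes) were searched against all transcripts with blastn 2.17.0+. Of these, 5 had a copy of at least 97% identity over at least 100 bp, and 32 shared at least 100 bp of exon with another gene. Counts of such genes are called uncertain where they are named.

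Totals ran from 3792582 to 6615093 counts per library. In simulated counts for 17627 genes with the means and spread of these libraries, the model recovered 56.7% of genes changed 1.5-fold, 82.1% of genes changed 2-fold and 97.0% of genes changed 4-fold for SynCom5-S1 against no bacteria, with 9 false calls among 176. For SynCom5-NS1 against no bacteria it recovered 41.8%, 88.1% and 97.0%, with 4 false calls among 166, and for SynCom5-S1 against SynCom5-NS1 56.7%, 86.6% and 100%, with 8 false calls among 179. A 4-fold change present in experiment A alone was recovered by the interaction test for 74.2%, 81.8% and 71.2% of genes in these contrasts, in the same order. The list with simulated changes was called in each contrast, and of the 19 unchanged lists 1, 0 and 0 were called. Genes were simulated independently of each other, whereas the estimated correlation within the real lists reached 0.907 (photosynthesis, SynCom5-S1 against no bacteria). The simulation therefore does not show how often camera at its preset correlation calls unchanged lists of correlated genes. Simulated libraries also shared 1 spread per gene and held no axis common to many genes. In the real libraries of the communities, a division unrelated to the groups gave 2623 calls, as described further on. The simulated shares recovered and false calls therefore do not give the rates among the real gene calls.

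Alternatives were DESeq2 1.42.0, relative log expression (RLE) scaling, limma-voom with sample quality weights, no filter on low counts (23128 genes), a filter of 1 CPM in 6 libraries (19023 genes), no experiment term, the replicate number as a block, only the 2 groups of a contrast, each experiment alone, a 2-fold threshold on calls and each library left out in turn. An alternative that leaves out organelle genes was planned and not run, since the table lists nuclear loci only. Chosen after seeing the data were fits without the SynCom5-NS1 libraries A2 and B3, which had the lowest quality weights, a fit with each library's mean log2 level of the photosynthesis list as a covariate, and the tests of gene families. Replicate libraries were compared by chi-square over genes with at least 20 counts in a pair, and the 45 pairs within groups differed by 2.34 to 21.6 times their degrees of freedom, so no pair was treated as 1 library.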

Results

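The data were read counts for 27206 Arabidopsis loci in 18 libraries of whole Col-0 seedlings, which had been grown on plates without bacteria, with the community SynCom5-S1 or with the community SynCom5-NS1. Each group held 6 libraries, 3 from experiment A and 3 from experiment B. Libraries held 4936106 ± 943717 counts without bacteria (SD, n = 6), 5153792 ± 325912 with SynCom5-S1 (n = 6) and 4697143 ± 482279 with SynCom5-NS1 (n = 6). The fewest were in SynCom5-NS1 A2, at 3792582, and the most in the no bacteria library A2, at 6615093. Suppressor and non-suppressor are the labels' words for the bacteria of SynCom5-S1 and SynCom5-NS1, and in this field they refer to whether a strain lessens the root growth inhibition that microbe-associated molecular patterns (MAMPs) such as flg22 cause. The comparisons ask how each community changed seedling transcripts relative to seedlings without bacteria, and how the communities differed from each other. Expression was tested for 17627 genes.

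The libraries differed along an axis that only partly followed the groups. The first principal component of log2 CPM held 25.1% of the variance, and on it the 6 libraries without bacteria lay between −35.7 and −1.69, those with SynCom5-S1 between −20.0 and 27.4 and those with SynCom5-NS1 between −5.40 and 44.4, with SynCom5-NS1 A2 highest. The mean log2 CPM of 31 photosynthesis genes, a measure of green shoot tissue, was 11.38 ± 0.18 without bacteria, 11.47 ± 0.24 with SynCom5-S1 and 11.55 ± 0.25 with SynCom5-NS1 (SD, n = 6 each). Over the 18 libraries this mean moved against the TMM scaling factor, with Pearson's r = −0.957 and Spearman's rho = −0.948. A negative relation is partly built in, since CPM values are divided by these factors and the photosynthesis genes are abundant, so no p is given. Without the libraries no bacteria B2 and SynCom5-NS1 B2, which lay farthest from the median, r was −0.943, and within experiments it was −0.987 in A and −0.948 in B. Within groups it was −0.986 without bacteria, −0.948 with SynCom5-S1 and −0.959 with SynCom5-NS1. The library SynCom5-NS1 B3 stood apart in defence genes: FRK1, a receptor kinase induced by flg22, was at 86.6 CPM there and at 5.51 to 29.1 CPM in the 5 other SynCom5-NS1 libraries, and SARD1, a transcription factor for salicylic acid synthesis, was at 40.0 CPM there.

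Seedlings with SynCom5-S1 had much lower transcript levels of single genes for iron uptake and for coumarins that mobilise iron, and higher levels of single cell wall genes, than seedlings without bacteria. IRT1 (AT4G19690), the main iron transporter of the root epidermis, fell from 218 ± 72.0 CPM without bacteria to 51.0 ± 15.6 CPM with SynCom5-S1 (SD, n = 6 each). CYP82C4 (AT4G31940), which makes the coumarin sideretin, fell from 61.9 ± 34.5 to 0.320 ± 0.785 CPM (SD, n = 6 each), and all 11 counts with SynCom5-S1 were in library B2. PRP1 (AT1G54970), a proline-rich cell wall protein of root hairs, rose from 0.776 ± 0.454 to 10.1 ± 5.06 CPM, and EXT12 (AT4G13390), an extensin, from 6.75 ± 2.95 to 52.3 ± 16.7 CPM (SD, n = 6 each). In edgeR quasi-likelihood tests with Benjamini-Hochberg adjustment, 274 of 17627 genes (1.55%) changed with SynCom5-S1, of which 101 rose and 173 fell. All 274 had the same sign in both experiments fitted alone, where 83 genes (45 higher and 38 lower) were called in experiment A and 133 (58 and 75) in experiment B. The same libraries gave these 274 calls, so agreement in sign is largely built in and is no independent replication. At a 2-fold threshold the calls were 62 higher and 61 lower.

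**Figure D1:**
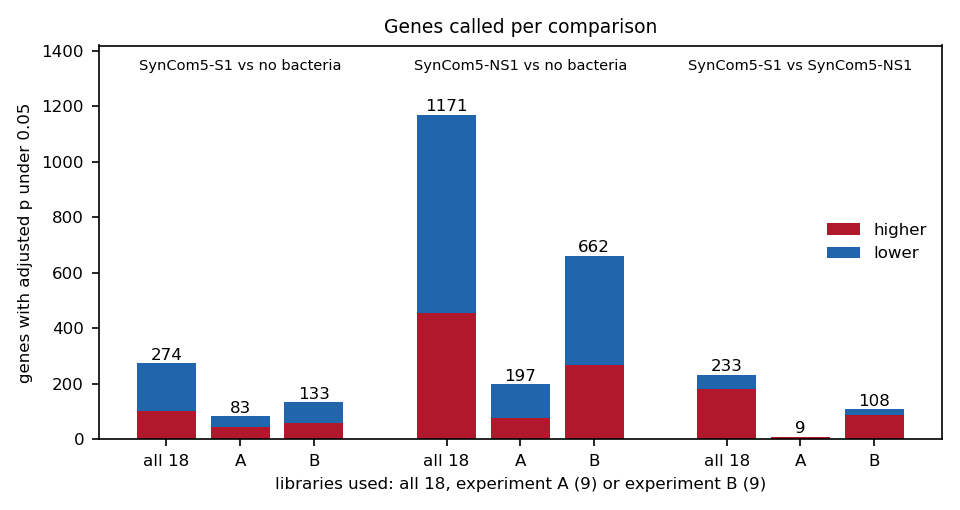
Number of genes with an edgeR adjusted p under 0.05 (vertical axis) for each comparison, with all 18 libraries, with the 9 libraries of experiment A and with the 9 of experiment B. Red parts of the bars are genes higher and blue parts genes lower in the first group named. The bars reach 274, 83 and 133 genes for SynCom5-S1 and 1171, 197 and 662 for SynCom5-NS1 against no bacteria, and 233, 9 and 108 between the communities.

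The iron deficiency list was called lower with SynCom5-S1. Of 19 measured genes, 9 fell and 0 rose (10 and 0 adjusted over the list alone), with a median log2 fold change of −0.78 (camera adjusted p = 3.91e-29, and adjusted p = 0.00226 with an estimated correlation). CYP82C4 had a log2 fold change of −7.38 (SE 0.450, edgeR adjusted p = 2.63e-08), and its total of 1773 counts without bacteria was 164 times its scaled total with SynCom5-S1 (95% counting interval 91.5 to 329). NAS2 (AT5G56080), a nicotianamine synthase, fell by 2.74 on the log2 scale (SE 0.327, edgeR adjusted p = 2.96e-05, with −2.11 in experiment A and −3.29 in B). IRT1 fell by 2.09 (SE 0.280, edgeR adjusted p = 0.000311, with −1.49 in A and −2.60 in B). S8H (AT3G12900), a hydroxylase of coumarin synthesis, fell by 2.62 (SE 0.426, edgeR adjusted p = 0.00217, with −1.83 in A and −3.33 in B). The endodermis and suberin genes, which mark a root tissue, had a median of −0.06 in the same contrast (camera adjusted p = 0.453), with 0 of 19 called.

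The root hair list was called higher with SynCom5-S1, with few members called. Of 10 measured genes, PRP1 and PRP3 rose and 0 fell (4 rose and 1 fell adjusted over the list alone). The median was 0.34 (camera adjusted p = 0.000172, and adjusted p = 0.362 with an estimated correlation). PRP1 rose by 3.59 on the log2 scale (SE 0.444, edgeR adjusted p = 8.17e-05). PRP3 (AT3G62680), another proline-rich root hair protein, rose by 1.35 (SE 0.258, edgeR adjusted p = 0.00809, with 1.33 in A and 1.37 in B). The largest increases outside the lists among genes with a symbol included other cell wall genes. XTH26 (AT4G28850), a xyloglucan endotransglucosylase, had 103 counts with SynCom5-S1 and 2 without bacteria, a ratio of scaled totals of 50.6 (95% counting interval 13.6 to 423). XTH13 (AT5G57540) and XTH12 (AT5G57530), of the same enzyme family, rose by 3.11 and 2.29, FLA6 (AT2G20520), a fasciclin-like arabinogalactan protein, by 3.55, and EXT12 by 2.94 (edgeR adjusted p from 8.65e-06 to 0.00221). G3Pp2 (AT4G25220), a glycerol-3-phosphate permease, rose by 2.96 (SE 0.408, edgeR adjusted p = 0.000138), and GLR2.3 (AT2G24710), a glutamate receptor-like channel, by 2.19 (SE 0.225, edgeR adjusted p = 5.62e-06).

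Among genes with a symbol, the largest decreases outside the lists included genes of detoxification and transport. GSTL1 (AT5G02780) and GSTU25 (AT1G17180), glutathione transferases, fell by 2.38 and 2.01 on the log2 scale with SynCom5-S1 (SE 0.305 and 0.254; edgeR adjusted p = 0.000103 and 7.84e-05). OCT1 (AT1G73220), an organic cation transporter, fell from 8.22 ± 1.53 to 1.84 ± 0.321 CPM (SD, n = 6 each), a log2 fold change of −2.15 (SE 0.231, edgeR adjusted p = 8.60e-06, with −2.29 in A and −1.98 in B). CEP1 (AT5G50260), a cysteine endopeptidase, fell by 1.95, and ATGLR1.2 (AT5G48400), a glutamate receptor-like channel, had a log2 fold change of −1.87 (edgeR adjusted p = 0.00377 and 0.00794).

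Auxin response genes shifted upward with SynCom5-S1 in the pooled libraries, and genes of several metabolic and growth lists shifted downward. Of 10 auxin genes, IAA19 (AT3G15540), an auxin-induced repressor, and GH3.2 (AT4G37390), an auxin-conjugating enzyme, rose by 0.84 and 0.75 (edgeR adjusted p = 0.0393 and 0.0443), 0 fell (3 rose and 0 fell adjusted over the list alone). The median was 0.19 (camera adjusted p = 0.00886, and adjusted p = 0.362 with an estimated correlation). This list's median was −0.13 in experiment A fitted alone (camera adjusted p = 0.664). Of 18 aliphatic glucosinolate genes, CYP79F1 (AT1G16410), which starts the pathway's core, fell by 1.42 (SE 0.307, edgeR adjusted p = 0.0219) and 0 rose (4 fell and 0 rose adjusted over the list alone). The median was −0.33 (camera adjusted p = 9.6e-05, and adjusted p = 0.513 with an estimated correlation). Of 19 abscisic acid genes 0 changed (1 fell and 0 rose adjusted over the list alone). The median was −0.13 (camera adjusted p = 0.00419, and adjusted p = 0.513 with an estimated correlation). P5CS1, a proline synthesis enzyme, was at −0.32 and HAI1, a phosphatase, at −1.01 (edgeR adjusted p = 0.0819 and 0.29). Of 10 flavonoid genes 0 changed (1 fell and 0 rose adjusted over the list alone). The median was −0.13 (camera adjusted p = 0.00731, and adjusted p = 0.227 with an estimated correlation), LDOX at −1.24 and MYB12 at −0.60 (edgeR adjusted p = 0.137 and 0.327). Of 19 cell cycle genes 0 changed (0 adjusted over the list alone). The median was −0.21 (camera adjusted p = 0.0031, and adjusted p = 0.59 with an estimated correlation). The cyclins CYCB1;2 and CYCB1;4 were at −0.42 and −0.45 (edgeR adjusted p = 0.58 and 0.589).

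MAMP-responsive and photosynthesis genes shifted slightly upward with SynCom5-S1 as lists, with no member called. The 24 MAMP genes had 0 calls (3 rose and 1 fell adjusted over the list alone). The median was 0.11 (camera adjusted p = 0.0197, and adjusted p = 0.669 with an estimated correlation). WRKY53, a defence transcription factor, was at 1.42 and CYP71A12, a camalexin enzyme, at −1.04 (edgeR adjusted p = 0.0863 and 0.0568). The 31 photosynthesis genes had 0 calls (0 adjusted over the list alone). The median was 0.10 (camera adjusted p = 0.0205, and adjusted p = 0.762 with an estimated correlation), with RBCS2B, a Rubisco subunit, at 0.20 and PETC, an electron transport protein, at 0.18 (edgeR adjusted p = 0.826 and 0.808). The other lists were not called: the medians were 0.01 for 18 pattern receptor genes (camera adjusted p = 0.814), 0.15 for 25 salicylic acid genes (0.322) and −0.04 for 24 jasmonate genes (0.467). They were 0.05 for 13 ethylene and defensin genes (camera adjusted p = 0.478), −0.05 for 23 indole glucosinolate and camalexin genes (0.532) and 0.05 for 18 phosphate starvation genes (0.578). They were 0.05 for 21 nitrogen genes (camera adjusted p = 0.589), −0.02 for 11 hypoxia genes (0.711) and −0.01 for 14 clock genes (0.34). For 10 sulphur starvation genes the median of −0.01 differed in sign from the mean of 0.15 and from the test (0.478). In these lists, adjusted over the list alone, 0 rose and 0 fell for pattern receptors, salicylic acid, jasmonate and endodermis, 1 and 1 for ethylene and phosphate, 0 and 1 for indole glucosinolates, hypoxia and the clock, 1 and 0 for nitrogen and 2 and 1 for sulphur. Single members called over all genes, named after their values were seen, were CHIB and PHT1;4, which fell, and SULTR1;2, SULTR1;1 and HRS1, which rose. The list calls with SynCom5-S1 were lost when 1 library was left out for MAMP genes (S1 A3 or the no bacteria libraries A3, B1 or B2; adjusted p up to 0.139), photosynthesis (S1 A2, B1 or B3 or no bacteria A1, A3 or B2; up to 0.394), auxin (S1 B2 or no bacteria B1; up to 0.0995) and abscisic acid genes (no bacteria A2; 0.053). Over these fits the medians ran from 0.05 to 0.25 for MAMP, 0.04 to 0.15 for photosynthesis and 0.05 to 0.25 for auxin genes. With experiments fitted alone they were lost in A for photosynthesis (camera adjusted p = 0.588) and in B for abscisic acid (0.229), flavonoids (0.13) and the cell cycle (0.18). Counts of WRKY53, CHIB and CYCB1;2 are uncertain, because exons of another gene overlap the first 2 on the opposite strand and CYCB1;2 has a near-identical copy. Among the named genes, CYP79F1, GH3.2 and IAA19 lost their calls in fits that left out 1 library (edgeR adjusted p up to 0.0647, 0.118 and 0.132).

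Seedlings with SynCom5-NS1 differed from seedlings without bacteria in single genes of defence and auxin, which were higher, and of iron uptake, nitrate uptake and root barriers, which were lower. Of the lists called, auxin response, iron deficiency and flavonoids kept their calls with an estimated correlation, and the others, defence, nitrogen and endodermis among them, did not. The defence gene WRKY53 (AT4G23810) rose from 2.30 ± 0.549 to 17.1 ± 12.9 CPM and FRK1 (AT2G19190) from 2.11 ± 1.19 to 25.5 ± 31.2 CPM (SD, n = 6 each). The auxin-conjugating enzymes GH3.2 and GH3.3 (AT2G23170) rose from 10.4 ± 2.12 to 54.9 ± 14.6 CPM and from 6.78 ± 1.21 to 29.0 ± 11.5 CPM (SD, n = 6 each). IRT1 fell from 218 ± 72.0 to 73.8 ± 29.5 CPM, the nitrate transporter NRT2.1 (AT1G08090) from 185 ± 70.5 to 57.2 ± 21.5 CPM, and CASP1 (AT2G36100), which builds the Casparian strip, from 35.0 ± 8.88 to 16.8 ± 6.80 CPM (SD, n = 6 each). In edgeR quasi-likelihood tests, 1171 of 17627 genes (6.64%) changed, of which 454 rose and 717 fell. All 1171 had the same sign in both experiments, which their selection largely builds in. With the experiments fitted alone, 197 genes were called in A and 662 in B. At a 2-fold threshold the calls were 189 higher and 175 lower.

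Defence lists were called higher with SynCom5-NS1 in the pooled libraries. Of 24 MAMP genes, 7 rose and CYP71A12 fell (12 and 2 adjusted over the list alone). The median was 0.54 (camera adjusted p = 2.02e-06, and adjusted p = 0.404 with an estimated correlation). FRK1 rose by 3.3 on the log2 scale (SE 0.535, edgeR adjusted p = 0.000979, with 1.89 in A and 4.21 in B), WRKY53 by 2.81 (SE 0.356, edgeR adjusted p = 6.03e-05, with 2.03 in A and 3.43 in B). RLP23 (AT2G32680), a receptor-like protein for a microbial pattern, rose by 3.14 (edgeR adjusted p = 0.007) and MYB51, an indole glucosinolate regulator, by 1.02 (edgeR adjusted p = 0.0462, with 0.07 in A and 1.88 in B). Of 18 pattern receptor and signalling genes 7 rose and 0 fell (7 and 1 adjusted over the list alone). The median was 0.36 (camera adjusted p = 0.00135, and adjusted p = 0.513 with an estimated correlation). Those that rose included the co-receptor kinases SOBIR1 at 1.00 and BKK1 at 0.84, the wall-associated kinase WAK2 at 0.94 and LORE (AT1G61380), a receptor of bacterial lipids, at 0.65 (edgeR adjusted p from 0.00434 to 0.0346). Of 25 salicylic acid genes 4 rose and 1 fell (11 and 1 adjusted over the list alone). The median was 0.48 (camera adjusted p = 0.00419, and adjusted p = 0.631 with an estimated correlation). PR1 (AT2G14610), a secreted defence protein, had 226 counts with SynCom5-NS1 and 6 without bacteria and rose by 4.98 (SE 1.1, edgeR adjusted p = 0.00915, with 3.6 in A and 6.12 in B). PR2, a glucanase, rose by 2.97 and SARD1 by 2.43 (edgeR adjusted p = 0.0107 and 0.0272), and UGT76B1 (AT3G11340), which glucosylates salicylic acid, fell by 1.21 (edgeR adjusted p = 6.70e-05, with −1.12 in A and −1.30 in B). Of 13 ethylene and defensin genes 4 rose and 1 fell (4 and 1 adjusted over the list alone). The median was 0.33 (camera adjusted p = 0.0226, and adjusted p = 0.404 with an estimated correlation). The ethylene synthesis gene ACS7 rose by 2.14, the defensin PDF1.3 by 1.62, and the basic chitinase CHIB fell by 0.97 (edgeR adjusted p from 0.00673 to 0.0225). ARCK1 (AT4G11890), a receptor-like kinase, rose by 3.52 outside the lists (SE 0.689, edgeR adjusted p = 0.00384, with 2.06 in A and 4.42 in B).

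Library SynCom5-NS1 B3 was far above the other SynCom5-NS1 libraries in PR1, at 32.7 CPM against 0.212 to 6.92 CPM, and in WRKY53, at 42.4 against 7.42 to 18.7 CPM. Without it, the salicylic acid and ethylene lists were no longer called against no bacteria (camera adjusted p = 0.164 and 0.147), and the medians were 0.23 for salicylic acid, 0.20 for ethylene, 0.31 for MAMP and 0.16 for pattern receptor genes. FRK1 was then at 2.61, PR1 at 3.72, ARCK1 at 2.59, RLP23 at 2.43, PR2 at 2.39, SARD1 at 1.5 and ACS7 at 1.56, and these calls were kept. Without SynCom5-NS1 A2 and B3 together, an alternative chosen after seeing the data, pattern receptors (camera adjusted p = 0.0569), salicylic acid (0.321), ethylene (0.195) and root hair genes (0.139) were not called. Higher calls with SynCom5-NS1 then made up 27.1% of all calls in place of 38.8%. Counts of WRKY53, SARD1, SOBIR1, WAK2 and CHIB are uncertain, because exons of a gene on the opposite strand overlap theirs.

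**Figure D2:**
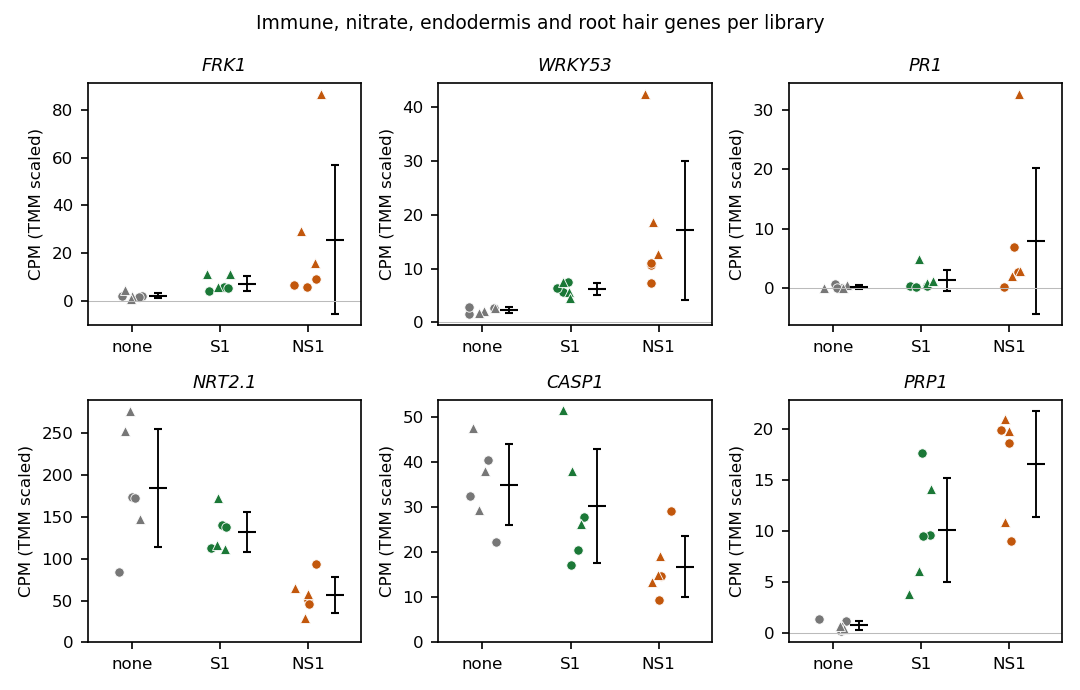
Expression in CPM (vertical axes, linear) of the defence genes FRK1, WRKY53 and PR1, the nitrate transporter NRT2.1, the Casparian strip gene CASP1 and the root hair gene PRP1 in each library without bacteria (none), with SynCom5-S1 (S1) and with SynCom5-NS1 (NS1). Circles are experiment A, triangles experiment B, and bars are mean ± SD with n = 6. The highest triangle of SynCom5-NS1 is library B3, in FRK1 at 86.6, in WRKY53 at 42.4 and in PR1 at 32.7 CPM.

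The auxin response list was called higher with SynCom5-NS1. Of 10 measured genes 4 rose and 0 fell (7 and 1 adjusted over the list alone). The median was 0.59 (camera adjusted p = 3.23e-10, and adjusted p = 0.0109 with an estimated correlation). GH3.2 rose by 2.39 (SE 0.176, edgeR adjusted p = 9.20e-08, with 2.70 in A and 2.02 in B) and GH3.3 by 2.08 (SE 0.255, edgeR adjusted p = 3.54e-05, with 2.52 in A and 1.55 in B). The repressors IAA19 and IAA2 rose by 1.03 and 0.54 (edgeR adjusted p = 0.00303 and 0.00362). The iron deficiency list was called lower, with 9 of 19 falling and 0 rising (10 and 2 adjusted over the list alone). The median was −0.65 (camera adjusted p = 1.4e-11, and adjusted p = 0.026 with an estimated correlation). The median was the same with CYP82C4, which had 2 counts in this group, at the end of its interval, since it is the lowest of the list. The scaled total of CYP82C4 was 801 times higher without bacteria (95% counting interval 221 to 6618). NAS2 fell by 3.1 (SE 0.350, edgeR adjusted p = 7.78e-06, with −2.63 in A and −3.48 in B), S8H by 2.18 (edgeR adjusted p = 0.00311), and F6H1 (AT3G13610), the enzyme that starts coumarin synthesis, by 1.62 (edgeR adjusted p = 8.45e-05, with −1.44 in A and −1.80 in B). FRD3 (AT3G08040), a citrate transporter that loads iron into the xylem, fell by 1.94 outside the list (SE 0.335, edgeR adjusted p = 0.000969, with −1.71 in A and −2.20 in B).

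**Figure D3:**
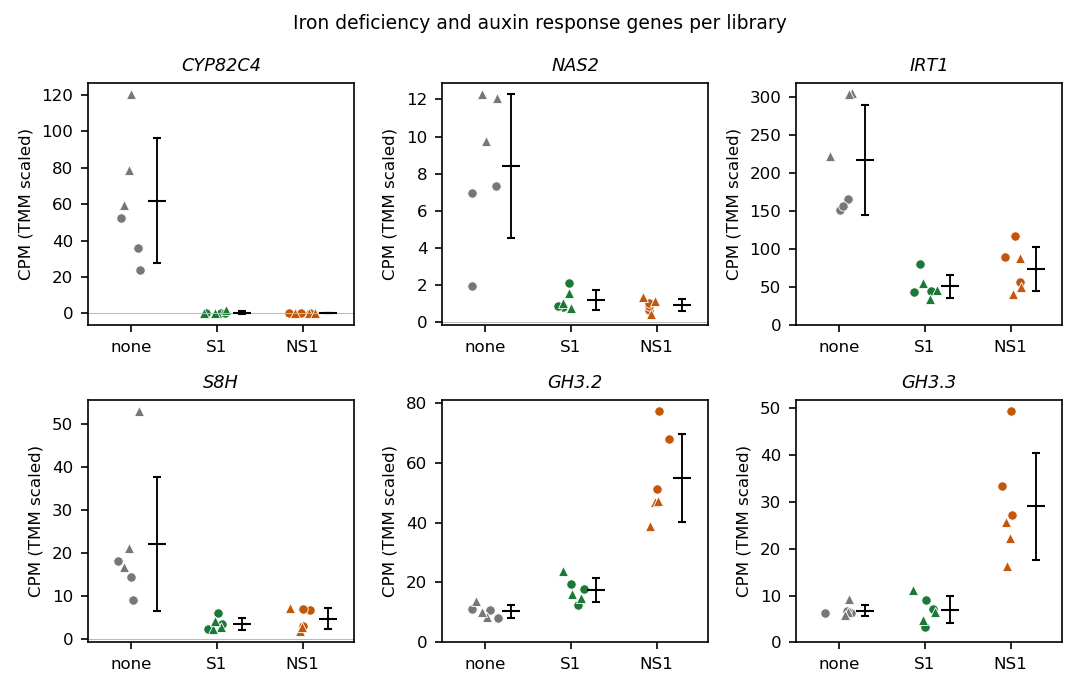
Expression in CPM (vertical axes, linear) of the iron deficiency genes CYP82C4, NAS2, IRT1 and S8H and of the auxin-conjugating genes GH3.2 and GH3.3 in each library without bacteria (none), with SynCom5-S1 (S1) and with SynCom5-NS1 (NS1). Circles are experiment A, triangles experiment B, and bars are mean ± SD with n = 6. IRT1 averaged 218 CPM without bacteria, 51.0 with SynCom5-S1 and 73.8 with SynCom5-NS1, and GH3.2 averaged 10.4, 17.4 and 54.9 CPM.

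The list of the endodermis and of suberin, the root's barriers, was called lower with SynCom5-NS1. Of 19 measured genes 5 fell and 0 rose (13 and 0 adjusted over the list alone). The median was −0.62 (camera adjusted p = 6.18e-09, and adjusted p = 0.227 with an estimated correlation). CASP1 fell by 1.08 (edgeR adjusted p = 0.0168, with −0.88 in A and −1.29 in B). The suberin genes KCS2 (AT1G04220), FAR5 (AT3G44550) and ABCG6 fell by 1.01, 0.93 and 0.82 (edgeR adjusted p = 0.00141, 0.00158 and 0.0292), with KCS2 uncertain because of an overlapping gene on the opposite strand. Root hair genes moved both ways: 3 of 10 rose and 2 fell (5 and 2 adjusted over the list alone). The median was 0.51 (camera adjusted p = 0.00964, and adjusted p = 0.513 with an estimated correlation). PRP1 rose by 4.33 (SE 0.425, edgeR adjusted p = 4.14e-06, with 3.97 in A and 4.74 in B), PRP3 by 1.49 and the expansin EXPA18 by 1.22. RHD6 (AT1G66470), a transcription factor that starts root hairs, fell by 1.66 (edgeR adjusted p = 0.00243, with −1.96 in A and −1.46 in B). XTH26 had 170 counts with SynCom5-NS1, 94.1 times its scaled total without bacteria (95% counting interval 25.6 to 783), and XTH13 and G3Pp2 rose by 4.12 and 3.44 (edgeR adjusted p = 1.57e-05 and 1.02e-05). Cell cycle genes had a median of −0.36 (camera adjusted p = 0.000172, and adjusted p = 0.513 with an estimated correlation), and of 19 the kinase CDKB2;1 fell, by 0.73 (edgeR adjusted p = 0.025), and 0 rose (1 and 0 adjusted over the list alone). The photosynthesis list, measured beside these root genes, had a median of 0.18 (camera adjusted p = 0.000664, and adjusted p = 0.669 with an estimated correlation) and 0 of 31 called (0 adjusted over the list alone). PSBO2 was at 0.27 and PETC at 0.25 (edgeR adjusted p = 0.315 each).

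The nitrogen, aliphatic glucosinolate, flavonoid and abscisic acid lists were called lower with SynCom5-NS1. Of 21 nitrogen genes 5 fell and 0 rose (7 and 0 adjusted over the list alone). The median was −0.08 (camera adjusted p = 0.00833, and adjusted p = 0.404 with an estimated correlation). NRT2.1 fell by 1.68 (SE 0.268, edgeR adjusted p = 0.000819, with −1.20 in A and −2.17 in B). The ammonium transporters AMT1;3 and AMT1;2 fell by 0.83 and 0.64, and the glutamine synthetase GLN1;4 by 0.59 (edgeR adjusted p from 0.0077 to 0.0459). Of 18 aliphatic glucosinolate genes 4 fell and 0 rose (11 and 0 adjusted over the list alone). The median was −0.58 (camera adjusted p = 2.78e-09, and adjusted p = 0.362 with an estimated correlation). Those that fell were CYP79F1 at −1.14 and the sulfotransferase SOT17 at −0.74 (edgeR adjusted p = 0.0304 and 0.00362), and the enzyme IPMI2 at −0.77 and the transporter BASS5 at −0.68 (edgeR adjusted p = 0.0478 and 0.0468). Of 10 flavonoid genes 4 fell and 0 rose (6 and 0 adjusted over the list alone). The median was −0.45 (camera adjusted p = 1.63e-05, and adjusted p = 0.026 with an estimated correlation). The anthocyanin enzymes DFR and LDOX fell by 1.72 and 1.71, the regulator MYB12 by 1.00 and F3H by 0.40 (edgeR adjusted p from 0.0117 to 0.0354). Counts of F3H are uncertain because of an overlapping gene on the opposite strand. Of 19 abscisic acid genes the cold-induced KIN1 and the transcription factor HB7 fell, by 1.26 and 0.80 (edgeR adjusted p = 0.00926 and 0.00809), and 0 rose (2 and 0 adjusted over the list alone). The median was −0.37 (camera adjusted p = 0.00591, and adjusted p = 0.527 with an estimated correlation).

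Outside the lists, OCT1 fell by 3.32 on the log2 scale with SynCom5-NS1 (SE 0.274, edgeR adjusted p = 1.41e-07, with −3.64 in A and −3.06 in B). The glutathione transferases GSTU25 and GSTU24 (AT1G17170) fell by 2.12 and 2.05, and the laccases LAC7 (AT3G09220) and LAC2 by 2.14 and 2.02 (edgeR adjusted p from 1.97e-06 to 0.00264). The phosphate transporter PHT1;3 (AT5G43360) had 0 counts without bacteria and 233 with SynCom5-NS1, at least 86.0-fold higher against a floor of 3 counts over the group, and 41 with SynCom5-S1, at least 13.4-fold higher. The lists not called with SynCom5-NS1 were jasmonate (median −0.15, camera adjusted p = 0.135), hypoxia (0.41, 0.218) and the clock (−0.03, 0.512), together with 3 lists whose signs differed. For indole glucosinolates the median was −0.06, the mean 0.13 and the test downward (camera adjusted p = 0.469), for phosphate starvation −0.03, 0.47 and upward (0.389), and for sulphur starvation −0.21, 0.06 and downward (0.558). PHT1;3 lies at the upper end of the phosphate list, so that the list's median does not depend on its fitted value. Some members of these lists were called over all genes, and they are named after their values were seen. AOC3 and VSP1 of the jasmonate list fell (0 rose and 2 fell adjusted over the list alone). SAD6 of the hypoxia list rose (2 and 0), as did PHT1;3 of the phosphate list (1 and 0). In the sulphur list the sulphate transporter SULTR1;1 rose and APR1 and APR3 of sulphate assimilation fell (1 and 2 adjusted over the list alone). In the indole list GSTF6, CYP81F2 and MYB51 rose and CYP79B3, CYP71A12, CYP79B2 and MYB34 fell (6 and 8 adjusted over the list alone), and 0 of 14 clock genes changed (0 adjusted over the list alone). List calls with SynCom5-NS1 were also lost without the no bacteria library B1 for ethylene (camera adjusted p = 0.0719), without SynCom5-NS1 B1 for abscisic acid (camera adjusted p = 0.0534) and without no bacteria A3 for root hair genes (0.0532). In experiment A alone the lists of salicylic acid (median 0.14, camera adjusted p = 0.613), ethylene (0.03, 0.409), nitrogen (−0.17, 0.324) and abscisic acid (−0.10, 0.409) were not called, and in B alone photosynthesis (0.10, 0.18) and the cell cycle (−0.25, 0.104). The nitrogen list was not called with the filter of 1 CPM in 6 libraries either (camera adjusted p = 0.0503). Among the named genes, calls were lost in fits that left out 1 library, with an edgeR adjusted p up to 0.0802 for ABCG6, 0.122 for AMT1;2, 0.114 for BASS5, 0.0892 for BKK1, 0.0502 for CASP1, 0.0691 for CDKB2;1, 0.0789 for CYP79F1, 0.0817 for DFR, 0.0545 for F3H, 0.111 for IPMI2, 0.121 for MYB51, 0.058 for PDF1.3, 0.0776 for SARD1, 0.0527 for SOBIR1 and 0.0852 for WAK2.

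**Figure D4:**
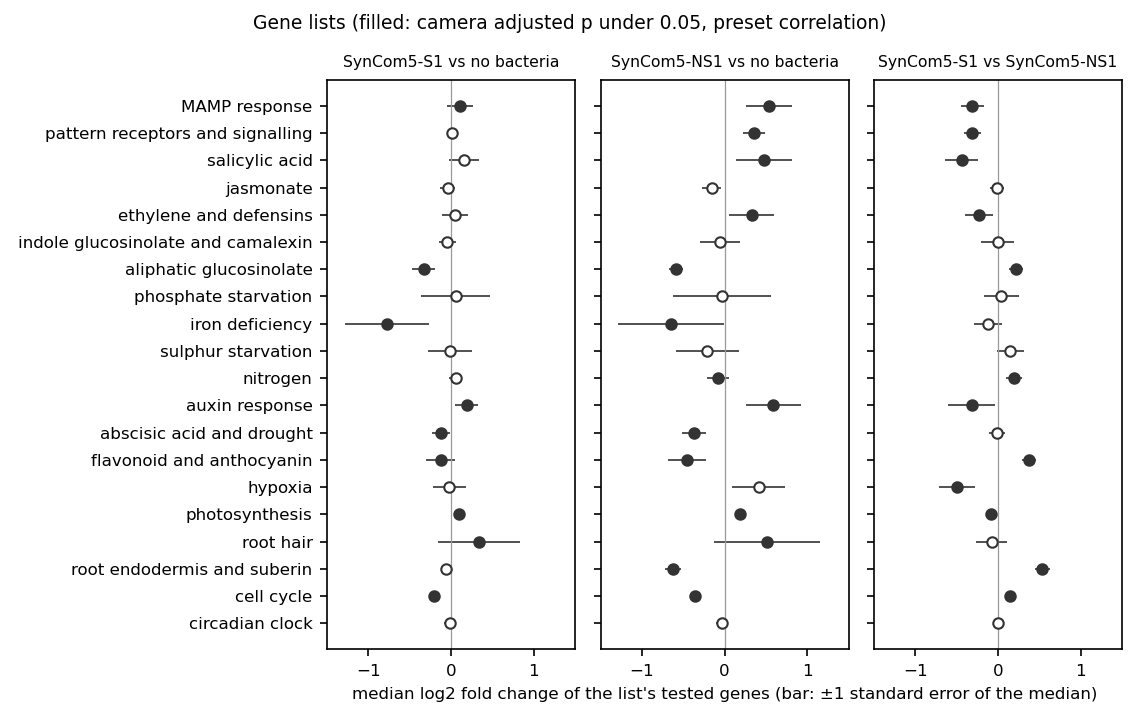
Median log2 fold change (horizontal axes) of each of 20 gene lists in the 3 comparisons, with bars of ± 1 standard error of the median over the list's genes. Filled circles are lists with a camera adjusted p under 0.05 at the preset correlation of 0.01, open circles are the others. Iron deficiency genes lie at −0.78 with SynCom5-S1 and −0.65 with SynCom5-NS1, and endodermis and suberin genes at −0.06 and −0.62.

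The changes with both communities overlapped. A total of 191 genes were called against no bacteria with both, 190 of them in the same direction (55 higher and 135 lower), which is 69.3% of the genes called with SynCom5-S1 and 16.2% of those called with SynCom5-NS1. Independent lists of these sizes would share 2.6 higher and 7.04 lower genes, and 20 simulations with unchanged groups and shared control libraries gave at most 0 shared genes. Neither value holds both the effects and the shared controls. With the controls divided so that each community had 3 control libraries of its own, 59 to 90 genes (median 73 over 18 fits of 9 divisions) were called in the same direction, out of medians of 129 and 509 calls. Across genes, which are not independent replicates, the log2 fold changes of both communities correlated at 0.705. Simulations with unchanged groups, where shared controls alone relate the communities, gave 0.499. With divided controls, where the communities share no library, the correlation was 0.393 to 0.570 (median 0.509). That value is not a second baseline, since a relation remained without shared controls. The covariance of the fold changes was 0.0793 against 0.0179 in simulations, a difference of 0.0614. With divided controls it was 0.0536 to 0.0724 (median 0.0663). Among the 9 genes called in the iron list with SynCom5-S1 and with SynCom5-NS1 were FRO2, the root's ferric reductase, at −1.67 and −1.44, PDR9, a coumarin exporter, at −1.31 and −1.40, and NAS1 at −1.15 and −1.33, named after their values were seen. The 1 gene called in opposite directions, AT5G67430, likewise named after its values were seen, fell by 1.11 with SynCom5-S1 and rose by 0.88 with SynCom5-NS1.

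Between the communities, the auxin response and defence lists were called lower, and the endodermis, nitrogen and aliphatic glucosinolate lists higher, with SynCom5-S1 than with SynCom5-NS1. Of these list calls only that of auxin was kept with an estimated correlation, and few or 0 members of the other lists were called. GH3.3 was at 7.00 ± 2.85 CPM with SynCom5-S1 and 29.0 ± 11.5 CPM with SynCom5-NS1, and NRT2.1 at 132 ± 23.7 and 57.2 ± 21.5 CPM (SD, n = 6 each). PGAZAT (AT2G41850), a polygalacturonase of abscission zones, was at 1.59 ± 0.597 CPM with SynCom5-S1, 14.5 ± 3.71 CPM with SynCom5-NS1 and 1.62 ± 1.08 CPM without bacteria (SD, n = 6 each). NSP3 (AT3G16390), a nitrile specifier protein of glucosinolate breakdown, was at 22.7 ± 3.19, 6.64 ± 0.700 and 18.2 ± 3.99 CPM in the same order (SD, n = 6 each). In edgeR quasi-likelihood tests of the difference, 233 of 17627 genes (1.32%) passed, 180 higher and 53 lower with SynCom5-S1. All 233 had the same sign in both experiments, which their selection largely builds in, and 9 genes were called in experiment A alone and 108 in B alone. Of the 233, 33 were also called for SynCom5-S1 and 166 for SynCom5-NS1 against no bacteria, 9 for both, and 43 for neither.

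The auxin response list was lower with SynCom5-S1 than with SynCom5-NS1, with 2 of 10 lower and 0 higher (4 and 0 adjusted over the list alone). The median was −0.32 (camera adjusted p = 1.54e-09, and adjusted p = 0.0109 with an estimated correlation). GH3.3 differed by −2.0 (SE 0.252, edgeR adjusted p = 0.000301, with −2.48 in A and −1.47 in B) and GH3.2 by −1.64 (SE 0.165, edgeR adjusted p = 1.02e-05, with −1.98 in A and −1.27 in B). Defence lists were called lower too in the pooled libraries. MAMP genes had a median of −0.31 (camera adjusted p = 1.75e-05, and adjusted p = 0.447 with an estimated correlation), with WRKY53 lower by 1.39 on the log2 scale (edgeR adjusted p = 0.0265, with −0.56 in A and −2.03 in B) and 0 of 24 higher (5 lower and 0 higher adjusted over the list alone). Pattern receptors had a median of −0.31 (camera adjusted p = 2.24e-05, and adjusted p = 0.404 with an estimated correlation), with LORE at −0.57 (edgeR adjusted p = 0.0332) and 0 of 18 higher (5 lower and 0 higher adjusted over the list alone). Salicylic acid genes had a median of −0.44 (camera adjusted p = 0.00309, and adjusted p = 0.616 with an estimated correlation), with UGT76B1 higher by 0.83 (edgeR adjusted p = 0.0104) and 0 of 25 lower (1 higher and 0 lower adjusted over the list alone). Ethylene and defensin genes had a median of −0.23 (camera adjusted p = 0.0174, and adjusted p = 0.404 with an estimated correlation) and 0 of 13 called (1 lower and 0 higher adjusted over the list alone). ACS7 was at −1.60 and the ethylene receptor ETR2 at −0.53 (edgeR adjusted p = 0.0785 and 0.255). Hypoxia genes had a median of −0.50 (camera adjusted p = 0.0233, and adjusted p = 0.592 with an estimated correlation) and 0 of 11 called (0 adjusted over the list alone). SAD6, a desaturase, was at −1.96 and the regulator LBD41 at −0.72 (edgeR adjusted p = 0.243 and 0.303).

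Endodermis and suberin genes were higher with SynCom5-S1 than with SynCom5-NS1 as a list. The median was 0.53 (camera adjusted p = 1.45e-12, and adjusted p = 0.119 with an estimated correlation), 0 of 19 called over all genes and 9 higher and 0 lower adjusted over the list alone. CASP4 of the Casparian strip was at 1.16 and the suberin hydroxylase CYP86A1 at 0.52 (edgeR adjusted p = 0.0635 and 0.0658). Of 21 nitrogen genes 3 were higher and 0 lower (4 and 0 adjusted over the list alone). The median was 0.19 (camera adjusted p = 1.75e-05, and adjusted p = 0.143 with an estimated correlation). NRT2.1 was higher by 1.21 (edgeR adjusted p = 0.0275, with 1.05 in A and 1.42 in B), the nitrate reductase NIA1 (AT1G77760) by 0.71 and the nitrate-responsive regulator HRS1 (AT1G13300) by 0.69 (edgeR adjusted p = 0.00396 and 0.0123). Aliphatic glucosinolate genes had a median of 0.22 (camera adjusted p = 5.74e-05, and adjusted p = 0.513 with an estimated correlation), with CYP79F2 higher by 0.70 (edgeR adjusted p = 0.0255) and 0 of 18 lower (1 higher and 0 lower adjusted over the list alone). Flavonoid genes had a median of 0.38 (camera adjusted p = 0.00132, and adjusted p = 0.119 with an estimated correlation) and 0 of 10 called (0 adjusted over the list alone). The chalcone synthase TT4 was at 0.42 and the flavonol synthase FLS1 at 0.46 (edgeR adjusted p = 0.279 and 0.291). Cell cycle genes had a median of 0.15 (camera adjusted p = 0.0353, and adjusted p = 0.669 with an estimated correlation) and 0 of 19 called (0 adjusted over the list alone). The cyclin CYCA1;1 was at 0.52 and CDKB2;1 at 0.39 (edgeR adjusted p = 0.513 and 0.552). Photosynthesis genes had a median of −0.09 (camera adjusted p = 0.022, and adjusted p = 0.762 with an estimated correlation) and 0 of 31 called (0 adjusted over the list alone). PSBR was at −0.15 and PSBO2 at −0.14 (edgeR adjusted p = 0.879 each), and the list's median was 0.06 in experiment B alone (camera adjusted p = 0.462).

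The iron deficiency list was not called between the communities, with a median of −0.12 (camera adjusted p = 0.135), 0 of 19 called and 2 lower and 0 higher adjusted over the list alone. The median of 10 sulphur genes was 0.15 (camera adjusted p = 0.135; 1 higher and 1 lower adjusted over the list alone) and that of 14 clock genes −0.00 (0.901; 0 adjusted over the list alone). Signs differed in 5 lists: the median, mean and test were −0.01, 0.01 and upward for jasmonate (camera adjusted p = 0.218; 1 higher and 0 lower adjusted over the list alone) and −0.00, −0.20 and upward for indole glucosinolates (0.713; 5 and 8). In the same order they were 0.04, −0.15 and downward for phosphate starvation (camera adjusted p = 0.389; 0 and 3), −0.01, 0.15 and upward for abscisic acid (0.423; 0 and 0) and −0.07, −0.01 and upward for root hairs (0.901; 1 and 0). Members called in these lists over all genes, named after their values were seen, were IGMT5, CYP79B3 and MYB34 of the indole list, which were higher with SynCom5-S1, and the phosphate transporters PHT1;4 and PHT1;3, which were lower. PHT1;3 differed by −2.68 (SE 0.529, edgeR adjusted p = 0.0231, with −1.86 in A and −3.74 in B).

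The largest differences outside the lists among genes with a symbol included metabolic enzymes and transporters. ATCSLB05 (AT4G15290), a cellulose synthase-like protein, was higher by 2.19 with SynCom5-S1 (SE 0.342, edgeR adjusted p = 0.00154), and its count is uncertain because part of its transcript is near-identical to CSLB06. PCK2 (AT5G65690), a phosphoenolpyruvate carboxykinase, and NSP3 were higher by 1.78 each (SE 0.171 and 0.148, edgeR adjusted p = 3.96e-06 and 8.32e-07). The sulfotransferase ST4B, the cytokinin hydroxylase CYP735A2, the wax enzyme CER4 and the squalene epoxidase-like SQP2 were higher by 1.75, 1.68, 1.65 and 1.54, and NLM1 (AT4G19030), an aquaporin, by 1.52 (edgeR adjusted p from 5.60e-05 to 0.0466). PGAZAT was lower by 3.19 (SE 0.307, edgeR adjusted p = 3.96e-06, with −3.42 in A and −2.96 in B), the defensin PDF1.4 by 2.0 and the β-glucosidase DIN2 by 1.51 (edgeR adjusted p = 0.0103 and 0.0108). BCAT-2, a branched-chain aminotransferase, was lower by 1.90 and THA1, a threonine aldolase, by 1.69 (edgeR adjusted p = 0.0226 and 0.0206), both with counts that are uncertain because of an overlapping gene on the opposite strand. Library SynCom5-NS1 B3 was highest in BCAT-2, THA1 and PDF1.4. There BCAT-2 was at 91.6 CPM against 6.32 to 25.1 in the 5 other SynCom5-NS1 libraries, THA1 at 38.1 against 6.55 to 18.0 and PDF1.4 at 35.7 against 4.29 to 9.78. Without this library the differences were −1.27, −1.31 and −1.41 in the same order, and the calls were kept.

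Between the communities the count of calls depended on single libraries: it was 121 without SynCom5-S1 B1, 127 without SynCom5-NS1 B2 and 150 without SynCom5-S1 B3. Lists no longer called without 1 library were salicylic acid (SynCom5-NS1 B3; camera adjusted p = 0.505), ethylene (S1 B1 or NS1 B3; up to 0.242), aliphatic glucosinolates (NS1 A2; 0.0527), hypoxia (S1 A2 or B1, or NS1 A3 or B3; up to 0.438), cell cycle (S1 A1, A3 or B2, or NS1 A2 or B2; up to 0.603) and photosynthesis (S1 A1, A3 or B2, or NS1 A1, A2 or B2; up to 0.462). Without NS1 B3, ACS7 was at −1.02 and SAD6 at −0.98. The medians without it were −0.08 for hypoxia, −0.15 for MAMP, −0.20 for pattern receptor, −0.21 for salicylic acid and −0.11 for ethylene genes. They were 0.01 for the cell cycle without S1 B2, 0.11 for aliphatic glucosinolates without NS1 A2 and −0.03 for photosynthesis without NS1 B2. In experiment A alone pattern receptors (median −0.04, camera adjusted p = 0.125), salicylic acid (−0.15, 0.324), ethylene (−0.13, 0.588), flavonoids (0.04, 0.46) and hypoxia (−0.48, 0.061) were not called, and in B alone the cell cycle (0.23, 0.474). Named genes that lost their calls in such fits had an edgeR adjusted p up to 0.0812 for BCAT-2, 0.0761 for CYP735A2, 0.076 for CYP79F2, 0.102 for LORE, 0.0787 for NRT2.1, 0.0708 for PHT1;3, 0.12 for SQP2, 0.0557 for THA1 and 0.0925 for WRKY53.

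The response to the communities was compared between the experiments with an interaction term. For SynCom5-S1, 2 genes differed between experiments: APR2 (AT1G62180), an enzyme of sulphate assimilation, had log2 fold changes of 0.63 in A and −0.81 in B, a difference of 1.44 (SE 0.225, edgeR adjusted p = 0.0308). The unnamed locus AT5G54130 had 0.38 in A and −1.05 in B, a difference of 1.43 (edgeR adjusted p = 0.0263). For SynCom5-NS1 the gene called was AT5G54130, with 0.26 in A and −1.14 in B (edgeR adjusted p = 0.0464). APR2 had 0.40 in A and −0.85 in B with SynCom5-NS1, a difference of 1.23 (SE 0.226, edgeR adjusted p = 0.0643), and its difference was not called between the communities (0.21, edgeR adjusted p = 0.963). For SynCom5-S1 against SynCom5-NS1, edgeR called 0 genes and DESeq2 1. At an unadjusted p under 0.05 there were 1267, 1461 and 814 genes in these contrasts, where 881.35 would pass by chance, and DESeq2 called 73, 39 and 1. Counts of APR2 are uncertain because of an overlapping gene on the opposite strand, and its adjusted p rose above 0.05 in 9 of the fits that left out 1 library, up to 0.182.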

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

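Of the tests in this part, the comparison of the iron list with the endodermis list, the measures of the iron list's shift, the fit with the photosynthesis mean as a covariate and the fit without SynCom5-NS1 A2 and B3 were chosen only after the result was seen.

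A total of 303 groups of 6 libraries were examined, for the log2 CPM of a named gene or for total counts. In 15 of them, all for a gene, 1 of the 6 libraries lay far from the others. Chance flags about 1 in 20 such groups, which is 15.15 here. The values are the gap to the nearest library as a share of the group's range. With SynCom5-NS1 they were 0.724 for G3Pp2 and 0.801 for IAA2 (A2 highest), 0.667 for OCT1 (A2 lowest), 0.724 for GLR2.3 (A1 lowest), 0.734 for KCS2 (A3 highest), 0.664 for ARCK1 (B3 highest) and 0.827 for CYP735A2 (B1 lowest). With SynCom5-S1 they were 1 for CYP82C4 (B2 highest, the other 5 libraries at 0 counts), 0.635 for PR2 and 0.628 for SARD1 (B3 highest) and 0.668 for RHD6 (B3 lowest). Without bacteria they were 0.674 for NAS2 (A3 lowest), 0.708 for MYB12 (B2 lowest), 0.718 for GH3.3 (B2 highest) and 0.662 for RHD6 (B1 lowest). By the interaction test, the effect of SynCom5-S1 in experiment A exceeded that in B by 1.44 on the log2 scale for APR2 and by 1.43 for AT5G54130, and the effect of SynCom5-NS1 by 1.39 for AT5G54130.

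The endodermis and suberin list was lower with SynCom5-NS1, with a median log2 fold change of −0.62 (camera adjusted p = 6.18e-09, and adjusted p = 0.227 with an estimated correlation). A smaller share of root tissue in these libraries would shrink this median once green tissue is accounted for. With the photosynthesis mean as a covariate the median was −0.72 and did not shrink. That mean followed the TMM factor (r = −0.957), partly by construction, and was not shown to measure the share of root tissue. The fit therefore does not decide this cause, which stays open. The root hair list, at 0.48, was not called in that fit (camera adjusted p = 0.0524), its members went both ways and it decides nothing. Without SynCom5-NS1 A2 and B3 the median was −0.75, which argues against these libraries as the sole cause. An effect of the bacteria on root barrier genes may account for the pattern, as a hypothesis found and tested on the same data, for a list call that an estimated correlation ends. A shift among root cell types was not tested and stays open. For the nitrogen genes and laccases that were lower with SynCom5-NS1, a smaller share of root tissue stays open too.

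Iron deficiency genes were lower with both communities, and with SynCom5-S1 the endodermis list, which a smaller share of root tissue would lower too, had a median of −0.0639 where the iron list had −0.78, above 0.5 of the iron median (−0.39), which argues against that cause for SynCom5-S1. With SynCom5-NS1 the endodermis median was −0.62 beside an iron median of −0.65. The same comparison therefore goes with a smaller share of root tissue there. With the photosynthesis mean as a covariate the iron median with SynCom5-NS1 was −0.78, and the iron list was still called (camera adjusted p = 1.04e-15). The members shifted by a median of 0.00489 (SE 0.0426). A measure tried first, the members' median distance of −0.43 from 0.5 of their own values without the covariate (SE 0.302), was inconclusive. The covariate was not shown to measure the share of root tissue, so that cause stays open for SynCom5-NS1. If seedlings held more iron, the ferritin genes FER1, FER3 and FER4, which store iron, would be higher, and their median was 0.43 with SynCom5-S1 and 0.24 with SynCom5-NS1. FER4, whose count is uncertain because of an overlapping gene, passed with SynCom5-S1 (log2 fold change 0.58, edgeR adjusted p = 0.0235) and 0 of the 3 genes passed with SynCom5-NS1, where FER4 was at 0.44 (0.0542). More iron in the seedlings and a response to bacteria at unchanged iron therefore cannot be told apart, and iron content was not measured in the data analysed here.

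More genes were called between the communities in experiment B, 108, than in A, 9. Without SynCom5-NS1 B3 the count in B was 43, still above 1.5 times that in A, which argues against this library as the sole cause, and in A it was 27 without SynCom5-NS1 A2. Libraries of B held fewer counts than those of A (means of 4828487 and 5029540), which argues against deeper libraries in B and leaves little to test by thinning to 3792582 counts, where the median count over 5 draws was 84 in B (71 to 101) and 9 in A (9 to 11). Pairs of libraries of a community in the same experiment differed by 2.70 to 8.97 times their degrees of freedom in A and by 3.37 to 13.2 times in B. By this measure a larger spread in A was not seen. The rise to 27 calls without SynCom5-NS1 A2 shows, however, that this library lowered the count in A. With B3 left out of B and A2 left out of A, the counts of 43 and 27 lay closer together. A stronger difference between the communities in experiment B stays open, and the interaction test of this contrast called 0 genes with edgeR (814 at an unadjusted p under 0.05, and DESeq2 1).

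Other divisions of the same 12 libraries of each comparison were drawn within experiments and tested with the libraries of the 2 groups alone. For SynCom5-S1 against no bacteria, 1 of 100 divisions, the real one with 372 genes, gave as many genes, and the highest of the others gave 1. For SynCom5-NS1 against no bacteria it was 1 of 100, the real one with 988 genes, and the highest other gave 0. Between the communities 3 of 100 gave as many genes as the real 131, and the highest other gave 2623. Against no bacteria these values argue against chance for each community. Between the communities the share was under 0.05, but the count of calls cannot exclude chance, since a division unrelated to the groups gave 2623 genes. That division points to a structure of the samples: it sets apart 6 libraries, S1 A1, A3 and B2 and NS1 A3, B1 and B3, which lie on the side of low photosynthesis means and high TMM factors. With the photosynthesis mean as a covariate, the contrast between the communities had 372 calls.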

How the results depend on the processing

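Of the tests in this part, the fits without SynCom5-NS1 A2 and B3 and with the photosynthesis mean as a covariate were chosen only after the result was seen.

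Named gene results that were called kept their direction in every alternative, and 2706 of the values compared kept their side of the threshold while 352 did not, 67 of them in experiment A alone and 38 in B alone, where fewer libraries were fitted. The kept direction was largely fixed in advance. The rule for the largest changes asked for the same sign in both experiments, and the alternatives reuse the libraries that gave the calls. Calls of genes in the order SynCom5-S1, SynCom5-NS1, between the communities and shared were 274, 1171, 233 and 190. They were 83, 197, 9 and 51 in experiment A alone, 133, 662, 108 and 101 in B alone and 123, 364, 97 and 80 at a 2-fold threshold. Limma-voom called 500 with SynCom5-S1, 351 between the communities and 324 shared. Between the communities DESeq2 called 371, the fit of only the 2 groups 131 and the covariate fit 372. The interaction counts of 2, 1 and 0 became 73, 39 and 1 with DESeq2, and 4 and 8 for SynCom5-S1 and SynCom5-NS1 without a filter, and for SynCom5-NS1 4 with the 1 CPM filter and 0 with RLE scaling. The 9, 14 and 12 lists called became 1, 3 and 1 with an estimated correlation and 2, 5 and 4 with fry. Fry kept iron deficiency and flavonoids with SynCom5-S1, and these, auxin, endodermis and aliphatic glucosinolates with SynCom5-NS1. Between the communities it kept auxin, flavonoids, endodermis and nitrogen, and the defence lists were lost in each contrast. With 1 library left out, the counts ran from 194 to 324, 797 to 1220, 121 to 329 and 130 to 219, interaction counts from 0 to 13, 0 to 16 and 0 to 0, and lists from 7 to 9, 13 to 15 and 9 to 13. The difference of APR2 between experiments stayed between 1.3 and 1.56. Reversed values were the auxin list with SynCom5-S1 in experiment A alone (−0.13) and, between the communities, the photosynthesis list (0.0564) and PSBR (0.0852) in B alone and TT4 (−0.00331) in A alone. Apart from fewer libraries or a higher threshold, the cause was not tested. The alternative without organelle genes was not run, and DESeq2 gave no adjusted p for ARCK1 and BCAT-2. At this depth and library number, the interaction tests recovered a 2-fold change in experiment A alone for 19.4%, 34.3% and 25.4% of simulated genes.

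With the replicate number as a block, the counts were 356, 1515, 365 and 254, each above that of the main fit. Whether the numbers stand for pairs is not settled: 10 of 18 pairs of same-numbered libraries correlated above 0.1 (−0.349 to 0.479). Of the 18 libraries, 5 correlated best with their own number in both other groups. The libraries numbered A2 correlated at 0.344 to 0.473 with each other, and those numbered B2 at −0.349 to 0.479.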

Other observations

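The tests of gene families in this part were all chosen after the data had been examined.

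The family of tau class glutathione transferases, enzymes of detoxification, was called lower with both communities. Families were formed from gene symbols, and 174 families with at least 8 tested members were tested by camera in the 3 contrasts. Of 522 tests 34 passed and 4 passed with an estimated correlation. Of 20 tau class genes (GSTU), 8 fell and 0 rose with SynCom5-S1 (median log2 fold change −0.65, camera adjusted p = 6.08e-28, and adjusted p = 0.00255 with an estimated correlation). With SynCom5-NS1 13 fell and 0 rose (median −0.83, camera adjusted p = 7.47e-23, and adjusted p = 0.00514 with an estimated correlation). GSTU8 fell by 1.32 with SynCom5-S1 and by 1.39 with SynCom5-NS1, GSTU19 by 0.83 and 0.89, and GSTU1 by 1.03 and 1.59 (edgeR adjusted p of 0.00123 or less for each). The laccase family, whose enzymes polymerise lignin and other phenolics, was called lower with SynCom5-NS1, where 6 of 12 fell and 0 rose (median −0.64, camera adjusted p = 1.92e-07, and adjusted p = 0.112 with an estimated correlation). Between the communities LAC7 was higher with SynCom5-S1, by 1.43, and the family's median was 0.57 (camera adjusted p = 5.36e-11, and adjusted p = 0.0248 with an estimated correlation).

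The family of genes named root hair specific (RHS) was called higher with both communities. Of 9 genes 4 rose and 0 fell with SynCom5-S1 (median 1.11, camera adjusted p = 3.79e-12, and adjusted p = 0.262 with an estimated correlation). With SynCom5-NS1 5 rose and 0 fell (median 1.37, camera adjusted p = 1.25e-06, and adjusted p = 0.631 with an estimated correlation). Among them RHS12 rose by 1.34 and 1.37 and RHS19 by 1.19 and 1.42. The family of cysteine-rich receptor-like kinases (CRK) was called higher with SynCom5-NS1, with 11 of 26 higher and 2 lower (median 0.41, camera adjusted p = 1.29e-05, and adjusted p = 0.806 with an estimated correlation). CRK14 rose by 2.16 and CRK5 by 2.03 (edgeR adjusted p = 0.00217 and 0.00159). CRK25, uncertain because of an overlapping gene, and CRK27 fell by 0.70 and 0.75. Serine carboxypeptidase-like genes (SCPL) had 3 of 31 higher and 0 lower with SynCom5-S1 than with SynCom5-NS1 (median 0.15, camera adjusted p = 0.000262, and adjusted p = 0.0248 with an estimated correlation). These were SCPL11, at 0.56, scpl3, and scpl1, at 1.38, the last of them uncertain because of a near-identical copy. The medians of these families had the same sign with RLE scaling and with DESeq2.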
